A study of Solanum lycopersicum with 3 samples.

How the data were processed

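RNA was measured in 3 libraries of tomato (Solanum lycopersicum) leaf primordia, all of the genotype slmp. Per the labels' protocols, each library came from 15 young primordia of leaf number 5 at the P5 stage (P counts plastochrons, the intervals between successive leaf initiations). The seedlings had been grown under 18 h of light and 6 h of dark and sprayed with water 1 h before collection. Libraries were made with a QuantSeq kit, which reads the 3′ ends of polyadenylated transcripts. Each transcript molecule gives about 1 fragment whatever its length, so values were not divided by gene length. No strand setting of the counting was given in the sources used here.

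The deposited table lists, per the file headers, 1 signal value for each locus in each library. Per the submitters' processing notes, Bowtie2, HTSeq and DESeq2 were used. Versions, the genome build and the annotation release are not given in the sources used here. The signal values deposited by the authors are not whole numbers, but every value in a column was a whole multiple of 1 step, within 0.001 of a step. The steps were 0.948, 1.04 and 1.08 in replicates 1, 2 and 3, which is the form that read counts take after division by 1 factor per library. The values are called scaled values here. The smallest value above 0 was 2 steps in each library and no value of 1 step occurred. Because of that gap no count model was fitted to test loci. Levels and spreads rest on the scaled values, on the log2(value + 1) scale where a spread is given. Steps were used as counts in the simulations of counting noise and in the checks of neighbouring loci and of zeros. Fold changes on this scale understate changes of low loci.

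The table holds 21717 loci and 3 summary rows of the counting program, which were left out of every total and test. The summary rows took part of the scaled total as follows: reads without a locus 22.2% ± 0.825 (SD, n = 3), reads of low alignment quality 23.3% ± 2.12, and ambiguous reads 2.58% ± 0.143. The loci took the remaining 52.0% ± 2.64. This total holds only the loci and the 3 summary rows listed, so these are not known to be shares of all reads sequenced. In steps, the loci summed to 2746410, 2574146 and 2499843 in replicates 1, 2 and 3, which is the depth behind the values. The level that 3 steps give was 2.84, 3.12 and 3.23, and values near it carry little precision. Limits of this kind cover counting error only. QuantSeq reads without molecular identifiers are not independent molecules.

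The loci carry tomato locus identifiers without gene names. The reference table of the assembly SLM_r2.1, with 41476 gene rows, paired 0 of the 21717 identifiers with a symbol. Single loci are therefore not named. The level of the mutated gene SlMP and the planned ratios between named paralogues are not analysed here for that reason. Of 29 gene lists fixed before the data were examined, 18 were defined by words in a gene description or symbol alone and had no members. The other 11 also held locus identifiers written down beforehand from general knowledge of the tomato family numbering, and 5 of these had at least 3 loci in the analysis: auxin response factors, Aux/IAA proteins, KNOX and BELL homeodomain proteins, boundary and leaf-margin regulators, and FRUITFULL-like and other MADS-box proteins. Membership could not be checked against a source of names, so these are lists of loci recorded under a family name. Members that these lists define by words could not be found either, so no list stands for a whole family. Recorded loci that the deposited table does not hold were left out, and the reason for their absence is not known here. Detection shares and list levels therefore hold only for loci that the table lists. No marker list of another tissue had enough loci to be used. The rule fixed for single genes took the 10 highest loci by mean and the 10 with the largest spread among loci with a mean of 20 or more. Without paired names it yields identifiers, of which 4 are printed and the others are summarised.

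A locus was called detected when its scaled value was at least 10 in each library. The spread was the SD of log2(value + 1) over the 3 libraries. Counting noise alone was simulated by drawing Poisson numbers of steps at each locus's mean and each library's step. For each list, the median level was placed among 10000 random lists of the same size from all loci. The median spread was placed among 10000 random lists matched on mean level in 20 bins. The resulting 2-sided random-list p-values were adjusted by the Benjamini-Hochberg method over the 5 lists, at a threshold of 0.05. Loci are not independent replicates, and these p-values describe the lists within these libraries. Neighbouring loci in identifier order, on the same chromosome by their identifier and with at least 20 steps in each library, were called near-identical when they differed by at most 3% in every library. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

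The list tests were tested on simulated data. A list of 200 loci changed 4-fold in 1 library lay at percentile 100.0 of spread. Of 100 random lists of 20 loci, 6 had an unadjusted level p under 0.05 and 6 an unadjusted spread p under 0.05. Random lists are drawn much as the comparison lists are, so that rate checks the calculation only. The simulated counts held counting noise alone, and the changed list was longer than any list analysed here. These checks therefore do not show what the tests can find in the short lists used. Of 50 copied neighbours, 49 were recovered, and 5 near-identical pairs arose among simulated independent loci.

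Alternatives were other scalings (equal library totals, and a median of ratios over these 3 libraries), other detection limits, other pseudocounts, another background, and leaving out each replicate. All 3 libraries form 1 group and no control group was analysed here, so no comparison between genotypes or treatments was made. The labels call the libraries replicates without saying whether they came from separate plants, so their spread may be partly technical. No columns were identical, and no columns of other samples were present.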

Results

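The transcriptome of young leaf primordia was measured in the tomato mutant slmp, with 3 replicate libraries of water-sprayed seedlings taken at the P5 stage of the fifth leaf. SlMP is the tomato counterpart of MONOPTEROS, a transcription factor of the auxin response factor family. The design holds this 1 group, so the data describe which loci are expressed in the mutant primordium, at what level, and how closely the replicates match. The scaled values of the 21717 loci summed to 2603014, 2673501 and 2693549 in replicates 1, 2 and 3. The level of SlMP itself is not analysed here, because no source used pairs its name with a locus. A 3′ end read outside a lesion would in any case not check the mutation.

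Most of the listed loci were expressed in every library. At least 10 scaled units were reached in all 3 libraries by 14910 loci, or 68.7% of the table, and 19778 loci (91.1%) were above 0 in all 3. The median locus had a mean of 33.3, with quartiles at 10.5 and 88.6, and 423 loci had a mean of 1000 or more. Expression was spread over many loci. The 10 highest loci of each library took 4.79% ± 0.175 (SD, n = 3) of its signal, and the 100 highest took 19.98% ± 0.692.

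The highest means belonged to the neighbouring loci Solyc01g109655, at 15716 ± 2243 (SD, n = 3), and Solyc01g109660, at 15712 ± 2244. These neighbours differed by only 7, 2 and 3 steps in replicates 1, 2 and 3, far less than independent counts of that size would. The other members of the 10 highest loci had means down to 9434. Their spread on the log2 scale, and that of the pair, lay between 0.16 and 0.31. That is around the median spread of 0.23 in the highest decile of detected loci.

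Auxin response factors are the DNA-binding proteins through which auxin acts on transcription, and SlMP belongs to this family. Of the 17 loci recorded under this family before the data were examined, 16 were in the deposited table and were analysed. Whether the 16 include SlMP could not be checked. Of the 16, 15 were detected in all 3 libraries. The highest had a mean of 329.6 ± 28.8 (SD, n = 3), followed by 318.8 ± 81.1 and 292.3 ± 31.8, and the lowest had 11.7. The list's median was 98.3, against 34.3 for random lists of the same size, and 12 of its 16 loci lay above the table's median. That median lay at percentile 99.28 of 10000 random lists, with an unadjusted random-list permutation p of 0.0146 and an adjusted p of 0.073 over the 5 lists, so it did not pass the threshold. Among detected loci only, the 15 detected members had a median of 102.8, at percentile 93.29 (random-list permutation p = 0.134, adjusted p = 0.403).

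Aux/IAA proteins are repressors that bind auxin response factors and are degraded in the presence of auxin. Of the 20 loci recorded under this family, 19 were analysed, and their levels ranged more widely. A single locus had a mean of 959.6 ± 71.3 (SD, n = 3), more than the next locus at 172.9 ± 33.8 and the third at 116.9 ± 72.4. At the other end, the lowest mean was 2.97, near the level of 3 steps. Detection in all 3 libraries was met by 12 of the 19. The list's median of 42.2 lay at percentile 71.14 of random lists (random-list permutation p = 0.578, adjusted p = 0.606). These loci as a set were thus not distinguishable from other loci in level. The mean of the list's log2 values lay at percentile 40.2, on the other side of the middle.

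The lists of leaf regulators did not pass the test of level. KNOX homeodomain proteins, which keep leaf cells in an undifferentiated state, and their BELL partners were represented by 3 loci, with means of 48.9 ± 0.962, 12.1 ± 2.92 and 6.47 ± 2.24 (SD, n = 3), of which 1 was detected in all libraries. Their median lay at percentile 18.01 (random-list permutation p = 0.36, adjusted p = 0.601). Boundary and leaf-margin regulators, which separate leaflets from each other, were represented by 4 of 5 recorded loci. Their highest means were 94.4 ± 14.8, 71.8 ± 19.4 and 44.4 ± 7.61, and the remaining locus was listed at 0 in replicates 1 and 2 and had a mean of 1.08. The median of 58.1 lay at percentile 69.69 (random-list permutation p = 0.606, adjusted p = 0.606), and the mean of log2 values at percentile 40.12.

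The list of FRUITFULL-like and other MADS-box proteins, a family of transcription factors, had the lowest median of the 5 lists, at 3.15. The 3 loci analysed had means of 10.8 ± 9.61, 3.15 ± 3.92 and 2.66 ± 2.42 (SD, n = 3), and none was detected in all 3 libraries. Each of the 3 was listed at 0 in replicate 2 and above 0 in replicates 1 and 3. The median lay at percentile 1.75 of random lists (random-list permutation p = 0.0354, adjusted p = 0.0885) and did not pass the threshold.

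**Figure D1:**
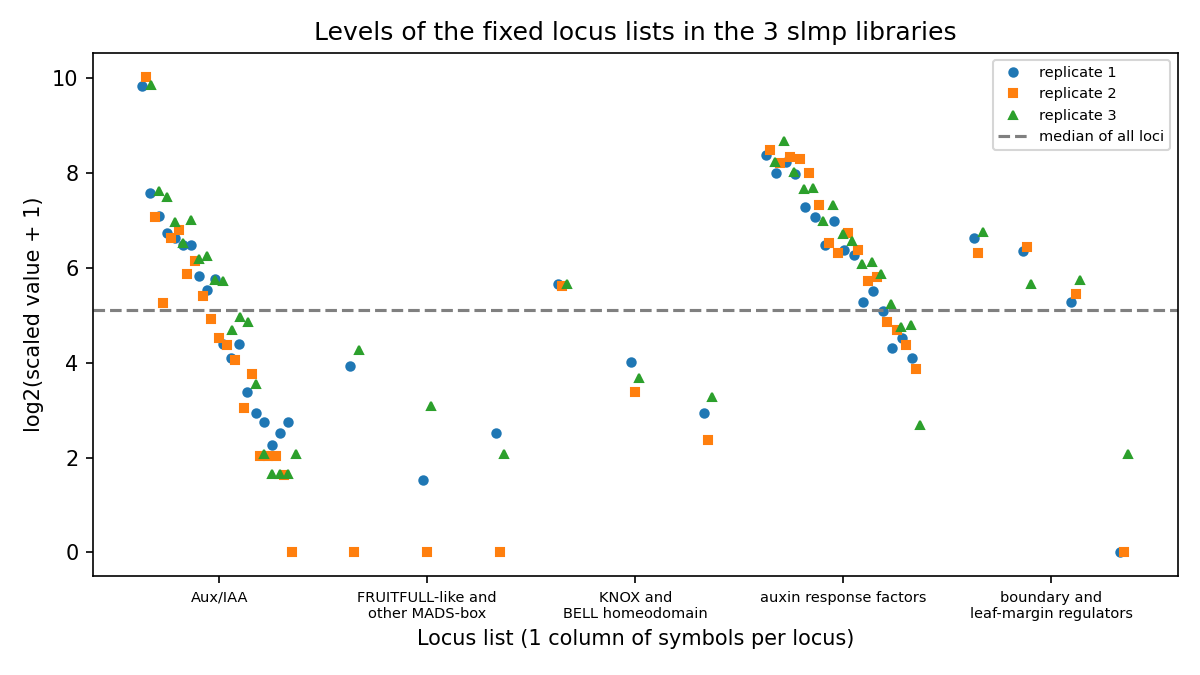
Scaled values on the log2(value + 1) axis for each locus of the 5 lists, with loci ordered by mean within a list and replicates 1, 2 and 3 shown as circles, squares and triangles. The dashed line is the median of all loci, and 12 of the 16 auxin response factor loci have means above that median, while the 3 loci of FRUITFULL-like and other MADS-box proteins have means below it and lie at 0 in replicate 2.

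The replicates resembled each other across loci, with replicates 2 and 3 the least alike. Across all 21717 loci, Pearson's r of log2 values was 0.934 between replicates 1 and 2, 0.931 between 1 and 3, and 0.917 between 2 and 3. Spearman's rho was 0.954, 0.953 and 0.938 for those pairs. These are correlations across loci, which are not independent replicates. Over detected loci the median SD of log2 values was 0.27, which corresponds to a factor of 1.21. Simulated counting noise alone gave a median of 0.14.

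Spread was compared with simulated counting noise by expression level. In the lowest decile of detected loci, with a median level of 16.8, the median SD was 0.31, against 0.28 from simulated counting. Loci in this decile lie near the minimum of 10 required in every library, which leaves out loci of wide spread at that level. In the next decile the median SD was 0.34, or 1.497 times counting noise. In the highest decile, with a median level of 585.2, it was 0.23 against 0.04, or 5.18 times counting noise. Between these last deciles the measured SD fell and the simulated SD fell further, from 0.23 to 0.04. The higher ratio therefore does not show more spread beyond counting at high levels.

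**Figure D2:**
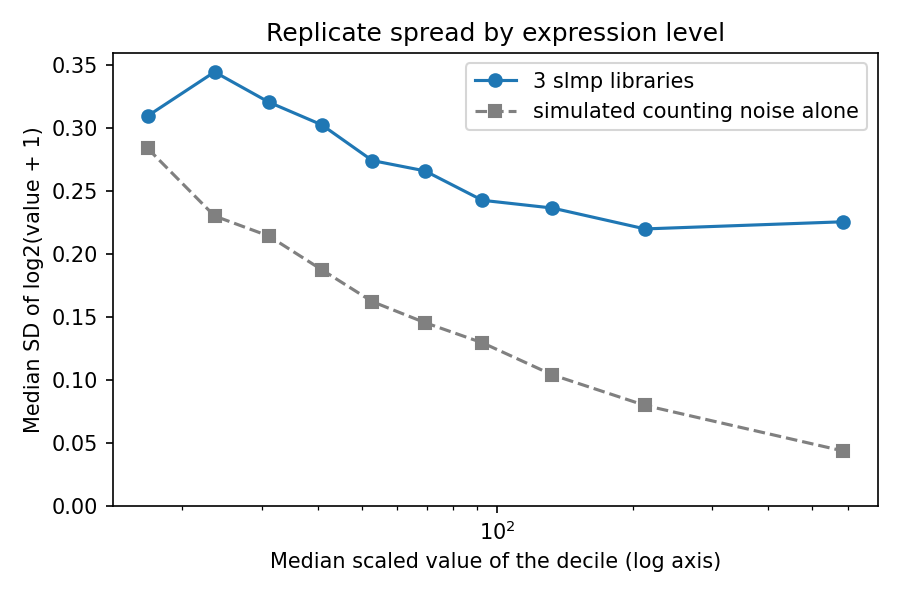
Median SD of log2(value + 1) over the 3 libraries against the median scaled value (log axis) for each decile of the 14910 detected loci. Circles are the measured values and squares are simulated counting noise alone. The medians were 0.31 against 0.28 in the lowest decile, whose spread the minimum of 10 limits, and 0.34 against 0.23 in the next. They were 0.23 against 0.04 in the highest decile.

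None of the 5 lists passed the test for more or less spread than loci of the same level. The median SD was 0.23 for the auxin response factor loci, against 0.26 for level-matched loci (random-list permutation p = 0.456, adjusted p = 0.76). It was 0.44 against 0.35 for the Aux/IAA loci (p = 0.236, adjusted p = 0.59 in the same permutation test). It was 0.32 against 0.42 for the KNOX and BELL loci (permutation p = 0.611, adjusted p = 0.764) and 0.33 against 0.34 for the boundary loci (permutation p = 0.941, adjusted p = 0.941). Some of these medians changed by more than 1.5 times when a library was left out. An SD over 2 libraries tends to lie below an SD over 3, so part of such a fall is built in. The Aux/IAA value was 0.27 without replicate 1 and 0.29 without replicate 2, and the boundary value was 0.09 without replicate 3. The loci of FRUITFULL-like and other MADS-box proteins had the widest spread, at 1.55 against 0.59 (permutation p = 0.0462, adjusted p = 0.231). With all 3 loci at 0 in replicate 2, this value follows the pseudocount, and it was 0.67 with a pseudocount of 5 and 2.51 with 0.25, neither of which passed the threshold. Without replicate 2 their spread fell to 0.31, at percentile 31.59 of matched lists. Without replicate 1 it was 2.19 and passed the threshold, with an adjusted permutation p of 0.021.

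Replicate 2 held many loci at lower values than both other libraries, a count chosen after the values were seen. Among the 13579 loci with a mean of 20 or more, 369 loci (2.72%) were over 2-fold lower in replicate 2 than in either other library, and 22 were over 2-fold higher. In replicate 3 the counts were 192 lower and 195 higher, and in replicate 1 they were 27 lower and 66 higher. Among 100 simulated sets of counting noise, the highest numbers lower and higher were 9 and 5 in replicate 1, 13 and 6 in replicate 2, and 15 and 4 in replicate 3, so each library exceeded them. Among the 10 loci with the largest spread, the lowest value was in replicate 2 at 8 loci and in replicate 3 at 2. Solyc08g062450 had the largest spread, at 154.5 in replicate 1, 43.6 in replicate 2 and a listed 0 in replicate 3. Solyc02g079240 followed, at 12.3, 2.08 and 114.2 in replicates 1, 2 and 3.

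**Figure D3:**
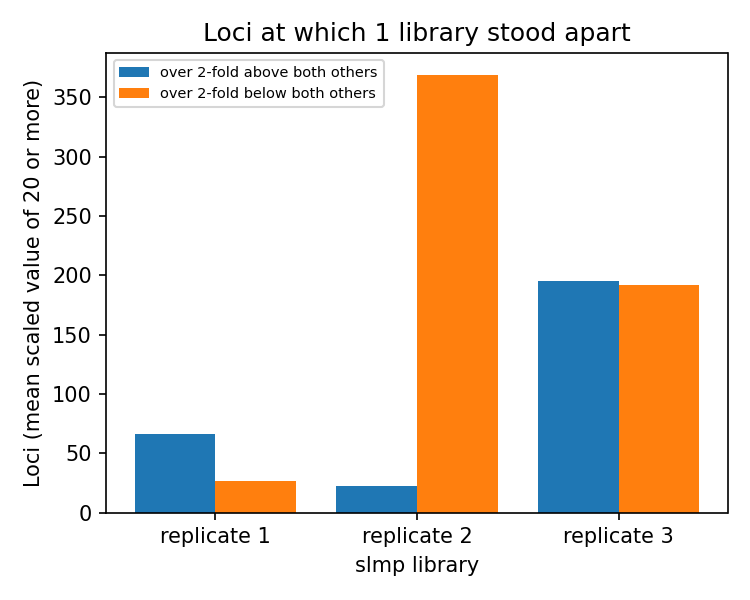
Number of loci, among 13579 with a mean scaled value of 20 or more, at which each library lay over 2-fold above or over 2-fold below both other libraries. Replicate 2 has 369 loci below and 22 above, while replicate 3 has 192 below and 195 above.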

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

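The reads that the counting program gave to no locus are data that no result above uses. Reads without a feature made up at least 21.2% of the scaled total in each library, reads of low alignment quality at least 21.4%, and ambiguous reads at least 2.43%. No library served as a control for these shares, so whether they are unusual was not tested. Groups of 3 libraries are too small for a test of single outlying samples.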

How the results depend on the processing

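Of 134 combinations of a result and a setting, 117 kept the direction and the side of the threshold, or stayed within 1.5 times of a count or the spread of a value. The tally took in list deviations only for the Aux/IAA loci, the FRUITFULL-like and other MADS-box loci, and the auxin response factor loci in replicate 2. Outside it, the deviation of the boundary loci in replicate 1 changed sign with detected members alone, without passing the threshold in either case. The median SD over detected loci rose from 0.27 to 0.34 with no filter on low values, and it ranged from 0.19 to 0.26 when each replicate was left out. The count of loci lower in replicate 2 was 110 among loci with a mean of 100 or more, where fewer loci are tested. Near-identical neighbours numbered 159 at a tolerance of 10%, which admits more pairs by construction. With the mean of log2 values in place of the median, the level percentile of the Aux/IAA loci fell to 40.2 and that of the boundary loci to 40.12, neither of them past the threshold before or after; the cause was not tested. With a pseudocount of 5 the boundary loci's spread moved to percentile 58.75; the cause was not tested. Leaving out each replicate moved the spread percentiles, given here after the value over all libraries. They were 22.79 and then 45.88 to 50.39 for auxin response factor loci, and 88.2 and then 26.78 to 88.76 for Aux/IAA loci. KNOX and BELL loci had 30.5 and then 23.62 to 64.35, and boundary loci had 47.05 and then 8.39 to 77.47. FRUITFULL-like and other MADS-box loci had 97.76 and then 31.59 to 99.82. No level of a list passed or reversed when a replicate was left out. Against detected loci, and for spread with detected members alone, the lists of KNOX and BELL proteins and of FRUITFULL-like and other MADS-box proteins had too few loci to give a value.

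The 2 calls of list deviations lost with a pseudocount of 5 are given with their values among the other observations. The alternatives chosen after seeing the data were the counting of near-identical neighbours once, the pseudocounts for the median SD, the tolerances for neighbours, the settings for loci lower in replicate 2, and those for list deviations. Not run were the planned dispersion fits and the per-locus count test, since the table holds scaled values without values of 1 step, and every alternative for SlMP and for ratios between paralogues, since no source pairs names with loci. No paired analysis was possible because all libraries belong to 1 group. Low values are limited by depth: 3 steps amount to 2.84, 3.12 and 3.23 scaled units in replicates 1, 2 and 3.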

Other observations

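The count of loci lower in replicate 2, its test against scaling, and the tests of the zeros, of neighbouring loci and of list deviations were chosen after the values were seen. The Aux/IAA loci sat low in replicate 2: their median deviation from each locus's own mean over the libraries was -0.31 on the log2 scale, and 14 of the 19 had their lowest value there. In replicates 1 and 3 the median deviations were 0.15 and 0.19, and over the 12 detected members they were 0.01 and 0.28, so the value in replicate 1 rests on low members. Among 10000 level-matched lists the value in replicate 2 lay at percentile 0.205 (random-list permutation p = 0.0048, adjusted p = 0.036 over 15 list and library combinations). It was -0.32 with equal library totals, -0.31 with a median of ratios and -0.33 over the 12 detected members, and with a pseudocount of 5 it was -0.18 and lost the call, at an adjusted permutation p of 0.249. The auxin response factor loci did not follow, with a median deviation of 0.12 in replicate 2 (adjusted permutation p = 0.452), although the difference between the families was not tested. The 3 loci of FRUITFULL-like and other MADS-box proteins had median deviations of 0.99 in replicate 1, -1.54 in replicate 2 and 1.54 in replicate 3, with adjusted permutation p-values of 0.305, 0.241 and 0.018. Deviations are taken from each locus's own mean, so the zeros of all 3 loci in replicate 2 raise the values of the other libraries. Their size depends on the pseudocount: they were 0.40, -0.60 and 0.73 with a pseudocount of 5, and 1.61, -2.71 and 2.19 with 0.25. The call in replicate 3 was lost with a pseudocount of 5 (adjusted permutation p = 0.057). Family membership of these loci was not checked against names.

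Replicate 2 had 369 loci over 2-fold below both other libraries and 22 above. Simulated counting noise gave at most 13 lower loci in 100 sets, but every library exceeded its simulated numbers, so that comparison does not bear on replicate 2 in particular. A wrong scaling factor would move all its loci alike. A uniform shift of 0.25 on the log2 scale was needed to bring lower loci below 2 for each higher one. The median detected locus of replicate 2 lay 0.02 above the mean of the other libraries, and its lowest decile median was -0.05. However, median-of-ratios factors recomputed from the scaled values were 1.010, 1.005 and 1.004 in replicates 1, 2 and 3, so the libraries were already aligned at their medians. A small median difference then follows from the scaling itself, and it cannot tell a right factor from a wrong one. The loss of values of 1 read does not account for the lower loci of replicate 2. Among loci with a mean of 100 or more there were 110 lower and 2 higher, a ratio of 55.0. The labels give the 3 libraries the same stage, tissue and treatment, so no biological explanation was tested, and differences in dissection, plant or handling between pools stay open.

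Neighbouring loci were near-identical more often than their levels alone would give. Of 7041 neighbouring pairs tested, 68 differed by at most 3% in every library, against at most 4 in 100 shuffled orders. Shuffling also breaks any likeness of level between neighbours. A simulated set of independent counts that kept the locus order, at the loci's own means apart from 200 changed loci, gave 5. Chance likeness of level can thus account for a few of the 68 pairs but not for most. Of these pairs, 32 were equal in all 3 libraries, and simulated independent counts at the same levels gave 0 such pairs in each of 100 sets. Equal counts are what the same reads counted at both loci would give, for example where annotated loci overlap. Shared regulation of separate transcripts would still leave counting noise between them. The counting program also listed ambiguous reads apart, and how it treated reads on overlapping loci is not given in the sources used here. The second loci of the 68 near-identical pairs held 1.72% of the signal, so totals were little affected, but the highest locus of the table is in such a pair.

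No library held a value of 1 step, although 2 steps was common. At loci where the other libraries together had 7 to 9 steps, with at least 2 steps in each, 471 of 2685 values were 0. Values of 2 steps numbered 401, against 418.1 to 421.2 in the model described next. A model of 0 reads alone gave 112.1 to 187.8 of them over dispersions from 0 to 0.15, and a model of 0 and 1 reads together gave 399.1 to 537.4. Taken by library, the zeros exceeded the highest number for 0 reads alone in each, at 92 against 53.3, 196 against 64.0 and 183 against 70.5 in replicates 1, 2 and 3. Replicate 3 lay within its range for 0 and 1 reads, 151.8 to 198.1. Replicate 1 lay below its range of 110.6 to 156.9 and replicate 2 above its range of 136.7 to 182.5. A candidate explanation is that values of 1 read were set to 0 before deposit, and it stays open, because replicates 1 and 2 miss their ranges in opposite directions. In all, 31 loci were listed at 0 in all 3 libraries.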
